A study of Homo sapiens with 6 samples.

How the data were processed

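RNA was sequenced from 6 libraries of the melanoma cell line A375, 3 from cells edited with CRISPR-Cas9 and a non-targeting control sgRNA and 3 from cells edited with an sgRNA against POLK. Per the labels' protocols, the cells were edited with the Alt-R CRISPR-Cas9 system, total RNA was extracted, and mRNA libraries were prepared with the TruSeq RNA V2 kit, which does not mark strand. Per the submitters' processing notes, FastQC, Trimmomatic, STAR and DESeq2 were used with the genome build GRCh38. The counting tool, its settings, the annotation release, any filter on genes and the tools' versions are not given in the sources used here.

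The authors deposited 1 table of raw counts per gene, not normalized, with a column for each library, an Ensembl identifier and a gene symbol. The values are whole numbers that sum to between 42852645 and 56891905 per library. The table holds 16934 genes, of which 210 have no symbol and 6 a symbol shared with another gene, and these were kept under their identifiers. Samples were grouped by the sgRNA stated in the labels, and columns were matched to samples by their names.

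Computation started from these counts in R 4.3.3. Genes with too few counts for a test were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 13930 genes (82.3%), 13904 of them protein-coding. Library sizes were scaled by the TMM method, with factors of 0.991 to 1.007. Groups were compared with edgeR 4.0.16's quasi-likelihood F test (robust, two-sided, no covariates), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of F. Expression levels are CPM on TMM-scaled library sizes. A gene with no count in a group was set against a floor of 3 counts over that group, which covers counting error only, and a gene with 1 to 3 counts in a group is given as a ratio with its exact 95% interval. Counts were simulated for this comparison with the spread between libraries of a group (13838 genes, 50 changed at each fold). Of genes changed 1.1-fold 44% were recovered, of those changed 1.25-fold 92% and of those changed 1.5-fold or 2-fold 100%. Of 13638 unchanged genes 16 were called. These rates hold only for that spread, which may be technical, and for far fewer changed genes than in the data. Paralogs, pseudogenes, overlapping genes and antisense genes can share reads under counting without strand and are uncertain.

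Before the data were examined, 31 gene lists were written from textbook knowledge, and the rule for named genes was set: POLK, the 12 genes with the largest log2 fold change in each direction among those with an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between groups, and the 3 members with the smallest p in each list. Some genes that this rule names are not reported here. Members named because they moved against their list or because of their known role (among them ATF4, ASNS, HSP90B1, CCND1, DUSP6, MDM2, GDF15, NGFR, AXL, POLH and POLI) were chosen after their values were seen. Lists were compared with all other genes by camera (limma 3.58.1) on log-CPM with a preset correlation of 0.01, and again with an estimated correlation, and tested on their own with fry. Tested on simulated counts (13839 genes) in which the p53 target list was lowered by 0.3 on the log2 scale, camera with the preset correlation called that list and 1 of the other lists. Markers of other cell types were also summed per library.

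Gene positions came from GENCODE 29, which uses the same build, and 13923 of the tested genes had one. After the data were examined, log2 fold changes of the 12324 genes with a mean of at least 1 CPM on chromosomes 1 to 22 and X were divided into segments by recursive binary splitting, with values limited to 0.75 around the median, at least 20 genes in a segment, and a threshold at the 99th percentile of the largest statistic in 100 shuffled gene orders. A segment was called shifted at a median of at least 0.1 from that of all genes. In 20 simulations with a planted shift of 0.4 over 160 genes, the boundaries were found within a median of 3 genes.

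Alternatives set before the data were examined were the size factors of DESeq2, library size alone, no filter, a filter on a mean CPM of 1, the replicate number as a block, DESeq2 1.42.0, limma-voom, each library left out in turn and, for lists, the estimated correlation and fry. Alternatives chosen after seeing the data were the removal of genes in shifted segments, the subtraction of segment medians, and edgeR's glmTreat against a fold of 1.25 or 2.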

Results

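Gene expression was measured by RNA sequencing in A375, an established human melanoma cell line that carries an activating BRAF mutation. The cells had been edited with CRISPR-Cas9 and either a guide RNA (sgRNA) against POLK or a non-targeting control sgRNA. POLK encodes DNA polymerase kappa, an error-prone polymerase that copies past damaged bases. Each group held 3 libraries, and each library held a count for 16934 genes. Total counts were 42852645, 55003324 and 48472454 in control libraries 1, 2 and 3 and 56891905, 46559658 and 48667179 in POLK sgRNA libraries 1, 2 and 3. Between 15953 and 16190 genes had at least 1 count in a library. Nothing in the labels says that the 3 libraries of a group came from separate cultures or separately edited cells. The p-values therefore set the group difference against only the spread between these libraries, which may be technical. The names of the count columns share 1 stem within each group, so each group may come from 1 edited population. If so, differences between the 2 populations cannot be told apart from an effect of POLK editing. Libraries of a group differed from each other by more than sampling noise, with a chi-square per degree of freedom of 2.14 to 4.37 over the 6 pairs. Across groups the value was 70.5 to 85.2 over the 9 pairs. The libraries of a group were counted as 3 samples. Their spread does not show that they came from separate cultures, so n = 3 counts libraries. The study concerns how oncogenic signalling regulates polymerase kappa and what the polymerase adds to drug resistance, and this comparison asks which transcripts differ in cells that received the POLK sgRNA.

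POLK itself (ENSG00000122008, chromosome 5, 75511756 to 75601144 on the plus strand, GRCh38) fell to 78.1% of its control level in the cells that received the POLK sgRNA. Its level was 23.3 ± 0.84 counts per 1000000 (CPM; SD, n = 3) with the control sgRNA and 18.2 ± 1.003 CPM (SD, n = 3) with the POLK sgRNA. The log2 fold change was −0.36 (SE 0.05), with an adjusted p of 7.9e-08 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The control libraries held 1004, 1312 and 1074 POLK counts and the POLK sgRNA libraries 1095, 803 and 889, and once scaled to depth the 2 groups did not overlap. An mRNA level does not measure how much of the gene was edited, and the position that the sgRNA targets within POLK is not given in the sources used here.

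**Figure D1:**
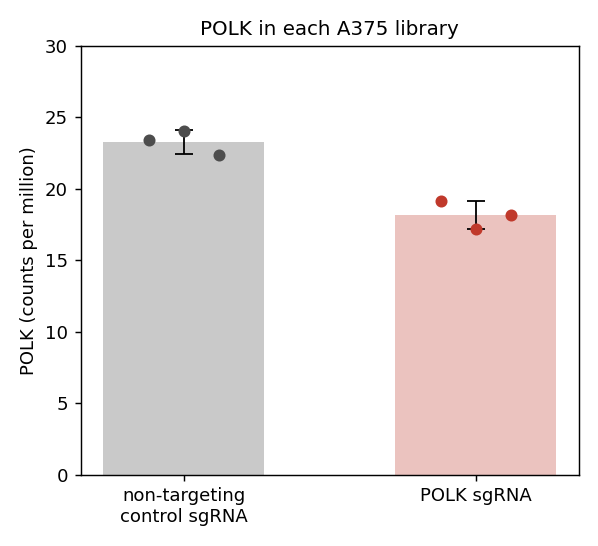
POLK expression in CPM (y axis) in the 3 control and 3 POLK sgRNA libraries (x axis); points are libraries, bars are group means and error bars are SD. The control libraries lie between 22.4 and 24.0 CPM and the POLK sgRNA libraries between 17.2 and 19.2 CPM.

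The difference between the groups extended over most of the transcriptome. Of 13930 genes tested, 4566 were higher and 4396 were lower with the POLK sgRNA (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), together 64.3%. Most of these differences were small, and 55.3% of the changed genes moved by less than 0.32 on the log2 scale. There were 953 genes changed at least 2-fold with POLK sgRNA, of which 506 were higher and 447 lower, and 525 when only genes with a mean of at least 1 CPM were tested. Tested against a minimum log2 fold change of 0.32, 1653 genes were higher and 1224 lower, and 543 genes passed a test against a fold of 2. The 2 groups did not overlap in 9435 genes (67.7%), where chance gives 10%. The biological coefficient of variation within groups was 2.42%, and the first principal component, which held 88.2% of the variance, separated the groups.

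The genes that rose most included several that were close to undetected in control cells. DCAF8L2 (X chromosome, 27590382 to 27748821) had no count in the 3 control libraries and 4.90 ± 0.60 CPM with the POLK sgRNA, at least 238-fold higher against a floor of 3 counts over the control group. NDN, an imprinted gene for the growth suppressor necdin, rose from 0.0253 ± 0.0277 to 13.9 ± 0.60 CPM, and GIPC3, which rests on 2 control counts, rose by a ratio of 238 with a 95% counting interval of 65.6 to 1973. MAGEA1, a cancer-testis antigen gene, rose from 0.437 ± 0.040 to 25.4 ± 0.43 CPM, ACSS3 from 0.495 ± 0.098 to 20.7 ± 0.89 CPM, and the homeobox gene HOXC12 from 0.147 ± 0.035 to 13.3 ± 0.31 CPM. FDCSP, COX7B2 and the lipid transporter gene ABCA8 reached 9.26 ± 1.05, 11.6 ± 0.41 and 6.06 ± 0.34 CPM from control levels under 0.2 CPM, and the 10 control counts of COX7B2 all lay in library 1. PPP4R3CP, a neighbour of DCAF8L2 on the X chromosome, rose on 1 control count by a ratio of 1946 (349 to 76881). PPP4R3CP, SSX1 (0.065 to 6.71 CPM), MAGEA1 and PCDHGB5 (0.107 to 4.24 CPM) share sequence or exons with close relatives, so their values are uncertain.

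PXDN, which encodes the basement membrane peroxidase peroxidasin, fell furthest (chromosome 2, 1631887 to 1744852). It had 59.1 ± 2.30 CPM in control cells and 0.107 ± 0.036 CPM with the POLK sgRNA, a log2 fold change of −9.11 (SE 0.10) with an adjusted p of 8.9e-37 in edgeR's quasi-likelihood test. COCH fell from 11.5 ± 0.47 to 0.0544 ± 0.0332 CPM, NCAM1, a neural cell adhesion molecule gene, from 5.94 ± 0.79 to 0.214 ± 0.093 CPM, and AMPH from 4.96 ± 0.09 to 0.0855 ± 0.0321 CPM. TEX15, a gene of germ cell meiosis, fell from 4.64 ± 0.45 to 0.0703 ± 0.0443 CPM. The potassium channel gene KCNJ8 fell on 1 count in the POLK sgRNA libraries, by a ratio of 443 (95% counting interval 79.0 to 17520), and PREX2, a Rac exchange factor gene, fell on 3 counts by a ratio of 131 (44.4 to 637). The netrin receptor gene UNC5D, ITM2A, DCAF12L2, TSPAN18 and the GDNF receptor gene GFRA1 fell from 2.19 to 2.99 CPM to under 0.09 CPM. Counting intervals and floors cover counting error only.

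Genes of the integrated stress response, which amino acid shortage and other stresses induce through ATF4, rose together. Of 25 members, 20 rose and none fell, with a median log2 fold change of 0.36. SHMT2, of mitochondrial one-carbon metabolism, rose from 235 ± 1.0 to 403 ± 4.4 CPM, the tRNA exporter gene XPOT from 192 ± 3.4 to 323 ± 8.6 CPM and ALDH1L2 from 18.7 ± 1.3 to 45.1 ± 0.95 CPM. ATF4 itself rose from 231 ± 5.4 to 332 ± 11 CPM and ASNS, which makes asparagine, from 93.1 ± 3.6 to 141 ± 1.9 CPM. The list was higher than other genes in camera, limma's competitive gene list test with a preset correlation of 0.01 (adjusted p = 1.3e-05), and not so with an estimated correlation (adjusted p = 0.33). Of the 20 members that rose, 5 (SHMT2, XPOT, ALDH1L2, TRIB3 and DDIT3) lie in raised segments of chromosomes 12 and 20 described below.

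Genes of the unfolded protein response, the chaperones and folding enzymes of the endoplasmic reticulum, moved the other way. Of 23 members, 18 fell and 1 rose, with a median log2 fold change of −0.29. HYOU1 fell from 575 ± 11 to 283 ± 2.6 CPM, HSPA5, the main chaperone of this compartment, from 1247 ± 13 to 803 ± 27 CPM, and PDIA6, a disulphide isomerase gene, from 427 ± 13 to 272 ± 1.5 CPM. HSP90B1, which lies in the raised segment of chromosome 12, was the member that rose, by a log2 fold change of 0.09, and 3 of the 18 that fell (PDIA6, DNAJB11 and HERPUD1) lie in lowered segments. The list was lower in camera with the preset correlation (adjusted p = 1.3e-05) and not with an estimated correlation (adjusted p = 0.45).

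Interferon-stimulated genes were higher. Of 28 members, 19 rose and none fell, with a median log2 fold change of 0.43. OAS1, OAS2 and OAS3, neighbouring genes for sensors of double-stranded RNA on chromosome 12, rose by log2 fold changes of 3.06, 2.21 and 1.15, and OAS3 had the highest level, at 42.2 ± 0.66 and 93.7 ± 3.5 CPM. The list was higher in camera with the preset correlation (adjusted p = 7.9e-05) and not with an estimated correlation (adjusted p = 0.23). OAS1, OAS2, OAS3, OASL and STAT2 lie in the raised segment of chromosome 12, and outside shifted segments 13 of 21 members rose, with a median log2 fold change of 0.36. The summed level of leukocyte markers was also higher in the POLK sgRNA libraries, at 62.6 ± 1.05 against 21.9 ± 0.02 CPM. That sum is mainly CD68 and LYZ, and of 6 tested markers 2 rose and 1 fell (camera, adjusted p = 0.91).

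Among NF-kB and inflammatory genes, 13 of 21 rose and 4 fell. The cytokine genes IL24 and IL1A rose from 5.66 ± 0.11 to 19.4 ± 0.69 CPM and from 2.49 ± 0.43 to 10.1 ± 0.37 CPM, and LIF fell from 60.3 ± 1.2 to 46.5 ± 0.89 CPM. The list did not pass in camera (adjusted p = 0.074).

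Transcripts that report activity of the MAPK pathway, which mutant BRAF drives in this line, were mostly lower. Of 24 members, 17 fell and 5 rose, with a median log2 fold change of −0.32. IL1RAP fell from 60.5 ± 1.3 to 35.0 ± 1.4 CPM, ETV5, a transcription factor gene, from 173 ± 2.1 to 120 ± 3.9 CPM and cyclin D1 (CCND1) from 425 ± 5.4 to 314 ± 5.0 CPM. PHLDA1 rose from 488 ± 8.7 to 834 ± 7.8 CPM and the ERK phosphatase gene DUSP6 from 145 to 194 CPM, and both lie in the raised segment of chromosome 12, while IL1RAP and ETV5 lie in a lowered segment of chromosome 3. The list was lower in camera with the preset correlation (adjusted p = 0.0059) and not with an estimated correlation (adjusted p = 0.33). Of 22 immediate early genes, 8 fell, among them IER3 and EGR3 with log2 fold changes of −0.45 and −0.67, and 5 rose, among them NR4A1, in the raised segment of chromosome 12, with 0.36 (camera, adjusted p = 0.22).

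Transcripts of p53 target genes were lower on balance, with 21 of 31 falling and 6 rising. The nuclease gene AEN fell from 211 ± 0.98 to 136 ± 2.2 CPM, the cell cycle inhibitor gene CDKN1A from 214 ± 7.1 to 158 ± 1.2 CPM and the apoptosis gene BAX from 180 ± 3.6 to 141 ± 1.6 CPM. GDF15 and MDM2, the gene for the ligase that degrades p53, rose by log2 fold changes of 0.66 and 0.22, and MDM2 lies in the raised segment of chromosome 12. The median was −0.22 (camera, adjusted p = 0.0074 with the preset correlation; adjusted p = 0.27 with an estimated correlation).

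Markers of the dedifferentiated melanoma state, a mesenchymal-like state with low pigment gene expression, were lower in 16 of 22 members and higher in 5, with a median log2 fold change of −0.37. INHBA, an activin subunit gene, fell from 182 ± 8.6 to 85.1 ± 1.7 CPM and LOXL2, a collagen-crosslinking oxidase gene, from 216 ± 7.3 to 117 ± 1.4 CPM. TGFBI rose from 71.6 ± 3.2 to 118 ± 1.7 CPM, and NGFR, a receptor often used as a marker of this state, from 5.64 to 19.0 CPM, and AXL, a receptor kinase gene, from 169 to 183 CPM. The list was lower in camera with the preset correlation (adjusted p = 0.0053) and not with an estimated correlation (adjusted p = 0.27). Of 18 melanocyte differentiation genes, 11 rose and 2 fell (camera, adjusted p = 0.074), and the list passed on leaving out control library 1 (adjusted p = 0.030). CDK2, in the raised segment of chromosome 12, rose from 66.7 ± 1.6 to 96.5 ± 0.58 CPM, OCA2, a pigment gene, rose from 0.312 ± 0.038 to 1.23 ± 0.20 CPM, and the pigment gene TYRP1 fell from 0.503 ± 0.075 to 0.0321 ± 0.0307 CPM.

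Enzymes of cholesterol synthesis were lower, with 15 of 25 falling and 3 rising and a median log2 fold change of −0.18. SQLE, which encodes squalene epoxidase, fell from 61.2 ± 0.94 to 44.1 ± 0.47 CPM. The list was lower in camera with the preset correlation (adjusted p = 0.0053) and not with an estimated correlation (adjusted p = 0.33).

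Other metabolic and stress lists did not pass in camera. Of 24 genes of glycolysis and the pentose phosphate pathway 7 rose, among them GAPDH (3870 ± 44 to 5838 ± 49 CPM) and PFKM, of which PFKM lies in the raised segment of chromosome 12, and 11 fell, among them GPI (669 ± 15 to 448 ± 3.8 CPM). Of 24 hypoxia genes 9 rose and 11 fell, with log2 fold changes of −0.47 for the glucose transporter SLC2A1, −0.38 for P4HA1 and 2.12 for CA12. Of 22 oxidative stress genes 6 rose and 9 fell, with 0.61 for TXNRD1 in the raised segment of chromosome 12, −0.40 for PGD and 0.58 for ABCC2. Of 12 xenobiotic response genes 3 rose, including AHR with 0.30, and 5 fell, including ABCC5, in the lowered segment of chromosome 3, with −0.68 and TIPARP with −0.47. Of 19 heat shock genes 3 rose, including HSPB1 with 0.31, and 9 fell, including DNAJA1 with −0.29 and BAG3 with −0.25. The adjusted p from camera was 0.51 for each of these 5 lists, and for glycolysis the median and the mean differed in sign.

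Nuclear genes of oxidative phosphorylation were higher in 12 of 34 and lower in 3, with log2 fold changes of 0.48 for ATP5B, which lies in the raised segment of chromosome 12, and 0.23 for NDUFV1 (camera, adjusted p = 0.17). Transcripts of the mitochondrial genome were lower in 5 of 13, with MT-CO2 at 1255 ± 107 and 803 ± 93 CPM (camera, adjusted p = 0.063). The list named mitochondrial genome passed in camera on leaving out control library 3 (adjusted p = 0.0086) or POLK sgRNA library 2 (adjusted p = 0.0057). MT-ND1 and MT-ND6 fell by 0.47 and 0.43 on the log2 scale and lost the call on leaving out control library 1 (adjusted p = 0.057 and 0.079), control library 2 (0.064 and 0.081), POLK sgRNA library 1 (0.060 and 0.069) or POLK sgRNA library 3 (0.053 and 0.080). Mitochondrial transcripts took 1.24 to 1.47% of the counts in control and 1.05 to 1.27% in POLK sgRNA libraries. Of 39 ribosomal protein genes 17 rose, led by RPL6 at 0.65 in the raised segment of chromosome 12. Another 8 fell, led by RPL35 at −0.64 and by RPS27A at −0.18 in the lowered segment of chromosome 2 (camera, adjusted p = 0.32).

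Lists of DNA repair and replication genes held members moving both ways, and none of them passed in camera. Of 23 translesion synthesis genes, the pathway in which polymerase kappa acts, 7 rose and 6 fell, with a median log2 fold change of 0.01 (camera, adjusted p = 0.85). PCNA, the clamp that recruits these polymerases, rose from 205 ± 1.4 to 287 ± 5.1 CPM and UBE2N from 160 ± 0.78 to 222 ± 5.7 CPM, and both lie in raised segments of chromosomes 20 and 12. REV1, a scaffold for these polymerases, fell from 33.6 ± 1.0 to 24.1 ± 1.3 CPM and lies in the lowered segment of chromosome 2. The related polymerase gene POLH, at 24.5 and 22.97 CPM, passed narrowly (adjusted p = 0.049 in edgeR's quasi-likelihood test) and lost the call on leaving out control library 2 or 3 (0.087 and 0.13) or POLK sgRNA library 1 or 2 (0.12 and 0.14). It also lost the call with the replicate number as a block (adjusted p = 0.056), library size alone (0.10), no filter (0.072) and DESeq2 (0.12). POLI, at 9.68 and 10.2 CPM, did not pass. Of 35 excision and mismatch repair genes 10 rose, including PARP1 (435 ± 2.8 to 662 ± 2.6 CPM), SMUG1 (30.8 ± 1.2 to 57.9 ± 1.5 CPM) and UNG (89.2 ± 2.3 to 127 ± 1.5 CPM), and 7 fell (camera, adjusted p = 0.51). SMUG1, UNG and TDG lie in the raised segment of chromosome 12, and 3 of the 7 that fell lie in lowered segments. Of 32 homologous recombination and Fanconi anaemia genes 14 rose, including FANCG, EXO1 and FANCI with log2 fold changes of 0.37, 0.24 and 0.21, and 4 fell (camera, adjusted p = 0.12). Of 26 replication stress and checkpoint genes 7 rose, including TIMELESS with 0.80, and 9 fell, including ETAA1 with −0.33 and MDC1 with −0.19 (camera, adjusted p = 0.95), and TIMELESS lies in a raised and ETAA1 in a lowered segment. Of 38 DNA replication genes 9 rose and 14 fell (camera, adjusted p = 0.51), and 6 of the 9, among them PCNA, RFC5 (37.6 ± 0.45 to 61.3 ± 2.0 CPM) and POLE (77.1 ± 1.4 to 114 ± 2.8 CPM), lie in raised segments. Of 32 mitosis genes 4 rose, including TPX2 with 0.56, and 14 fell, including BUB1 with −0.46 and ASPM with −0.29 (camera, adjusted p = 0.11), and TPX2 lies in a raised and BUB1 in a lowered segment. Of 16 replication-dependent histone genes 1 rose, HIST1H1D at 1.06, and 3 fell, including HIST2H2AC at −1.01 and HIST2H2BE at −0.61 (camera, adjusted p = 0.53), and values of these near-identical genes are uncertain.

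Among 25 extracellular matrix genes 11 rose, including COL5A1 (36.7 ± 0.98 to 86.1 ± 2.4 CPM), and 9 fell, including BGN (44.7 ± 0.74 to 15.1 ± 1.4 CPM) and COL4A1 (592 ± 12 to 386 ± 10 CPM; camera, adjusted p = 0.84). Of 17 tested genes near POLK on chromosome 5, 4 rose and 8 fell (camera, adjusted p = 0.38), with log2 fold changes of −0.48 for F2R and 2.51 for F2RL2. For the matrix, glycolysis, DNA replication and leukocyte lists the median, the mean and the test did not all share a sign. Adjusted over the list alone, the counts of members that rose and fell were those given for all lists except the mitochondrial genome (0 and 0), genes near POLK (4 and 9), oxidative phosphorylation (12 and 2), oxidative stress (7 and 9) and translesion synthesis (7 and 5).

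**Figure D2:**
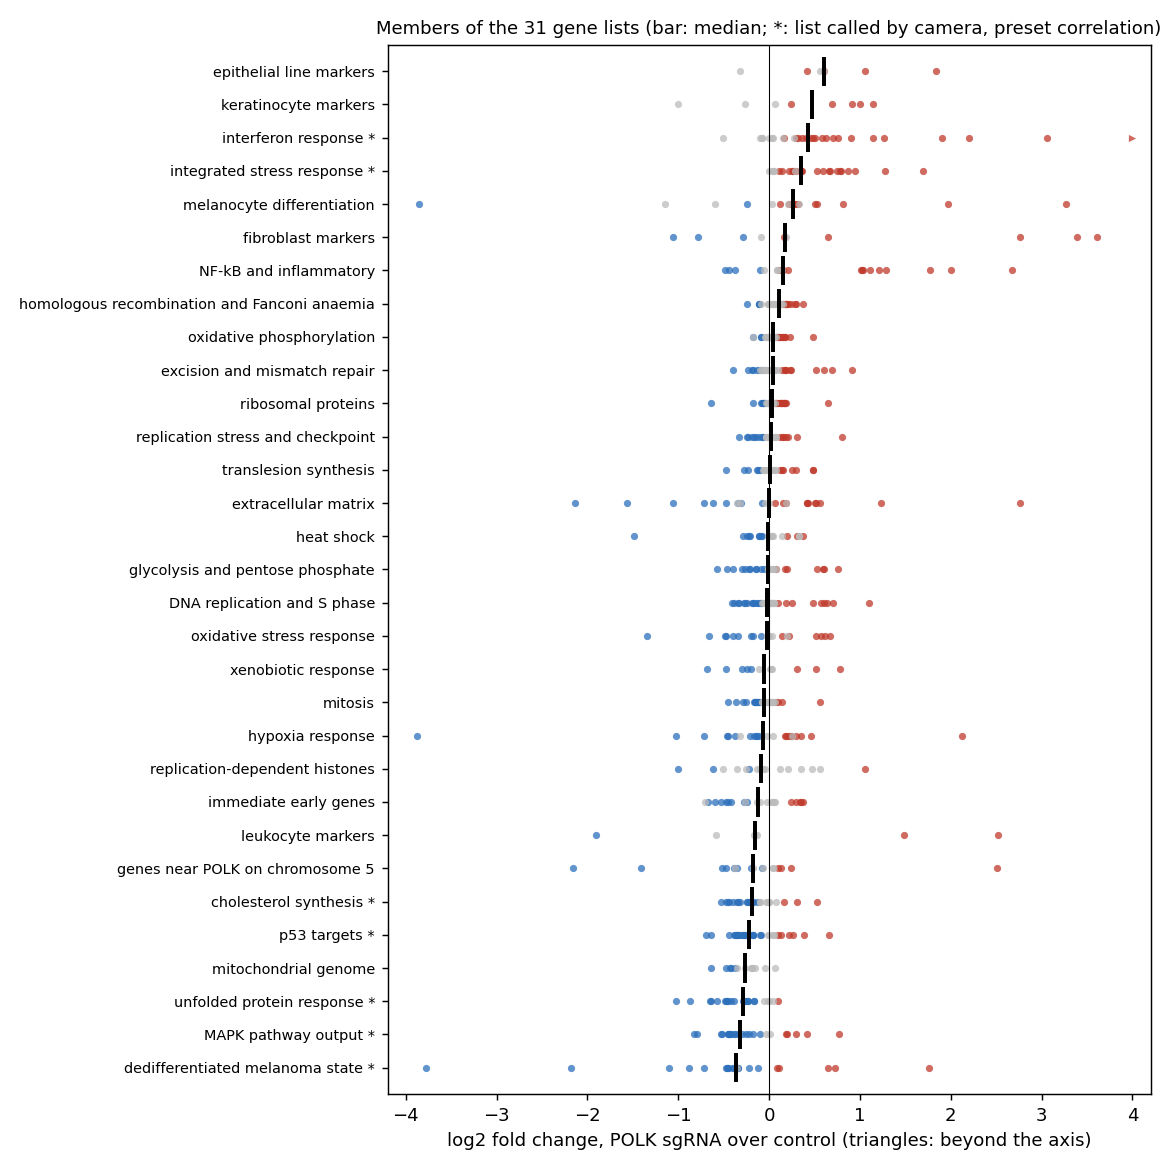
Log2 fold change (x axis, POLK sgRNA over control, from fits to 3 libraries per group) of every tested member of the 31 gene lists (y axis, ordered by median); red points rose, blue points fell, grey points did not pass the test, black bars are medians and 1 member beyond 4 is drawn as a triangle. The 7 lists with an asterisk passed in camera with the preset correlation, from a median of −0.37 for the dedifferentiated melanoma state to 0.43 for the interferon response.

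Markers of other cell types were measured as summed CPM. Among leukocyte markers, LYZ rose (3.42 ± 0.22 to 19.7 ± 0.96 CPM), as did CD68 (13.99 ± 0.23 to 39.3 ± 2.0 CPM), while the monocyte marker CD14 fell from 0.354 ± 0.058 to 0.0917 ± 0.0090 CPM, so that 2 of 6 tested members rose and 1 fell (camera, adjusted p = 0.91). Epithelial markers summed to 115 ± 1.5 CPM in control and 178 ± 3.3 CPM in POLK sgRNA libraries, led by KRT18 (82.9 ± 1.6 to 127 ± 3.2 CPM), CLDN4 and KRT8, and 4 of 7 rose (adjusted p = 0.067 in camera). KRT18 and KRT8, with log2 fold changes of 0.61 and 0.42, lie in the raised segment of chromosome 12 (median 0.56), as do LYZ, LUM and DCN. Keratinocyte markers summed to 153 ± 2.2 and 188 ± 0.78 CPM, and 5 of 8 rose, including DSP, KRT14 and KRT10 with log2 fold changes of 1.01, 0.91 and 0.24 (adjusted p = 0.090 in camera). Fibroblast markers summed to 408 ± 5.6 and 413 ± 6.9 CPM, with 5 of 10 rising, including LUM from 0.423 ± 0.046 to 4.50 ± 0.28 CPM and COL6A3 from 1.15 ± 0.32 to 7.68 ± 0.50 CPM, and 3 falling, including PRRX1 from 190 ± 1.7 to 156 ± 4.4 CPM (adjusted p = 0.42 in camera). Melanocyte differentiation genes summed to 1377 ± 7.6 and 1513 ± 26 CPM, most of it SOX10.

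Neighbouring genes shared a shift in expression on 6 chromosomes, over long stretches except on chromosome 19. Of 31 segments found along the chromosomes in 12324 genes, 8 had a median at least 0.1 (log2) away from that of all genes. The long arm of chromosome 12 from 47.1 to 133.2 Mb was raised, with a median log2 fold change of 0.56 (1.48-fold) over 486 genes, 98.4% of which had a positive log2 fold change and 95.9% of which also passed the test. On chromosome 20 the first 34.1 Mb were raised by 0.61 (133 genes) and the remainder by 0.16 (189 genes), and a run of 35 genes on chromosome 19, which begins at ZNF577, was raised by 0.36. Genes were lower along chromosome 2 up to 156.6 Mb, by a median of −0.25 (509 genes), at the end of chromosome 3 from 180.6 Mb, by −0.46 (87 genes), and on chromosome 16 from 53.6 to 75.8 Mb, by −0.43 (155 genes), and from 77.2 Mb to the end, by −0.11 (75 genes). In each shifted segment the 3 POLK sgRNA libraries agreed within an SD of 0.030, and no control library lay more than 0.0145 from the control mean. The strongest boundary had a statistic of 24.5, and the highest in 100 shuffled gene orders was 6.48. On chromosome 5 the median was −0.04 over 175 genes before POLK and −0.021 over 418 genes beyond it.

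The shifted segments held 1853 of the tested genes (13.3%), and 84.1% of them passed the test, against 61.3% of the genes elsewhere. Outside these segments 3691 genes were higher and 3713 lower of 12077 tested. All 7 list calls made with the preset correlation also passed when genes in shifted segments were left out, with adjusted p between 4.6e-05 and 0.0026. In the same camera test the mitochondrial genome (lower, adjusted p = 0.045) and keratinocyte markers (higher, adjusted p = 0.026) then passed as well. With segment medians subtracted, mitosis (lower), NF-kB and inflammatory genes (higher) and the mitochondrial genome (lower) passed, each with an adjusted p of 0.045. The segments were sought after the data had been examined, and the files hold no measurement of DNA copy number.

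**Figure D3:**
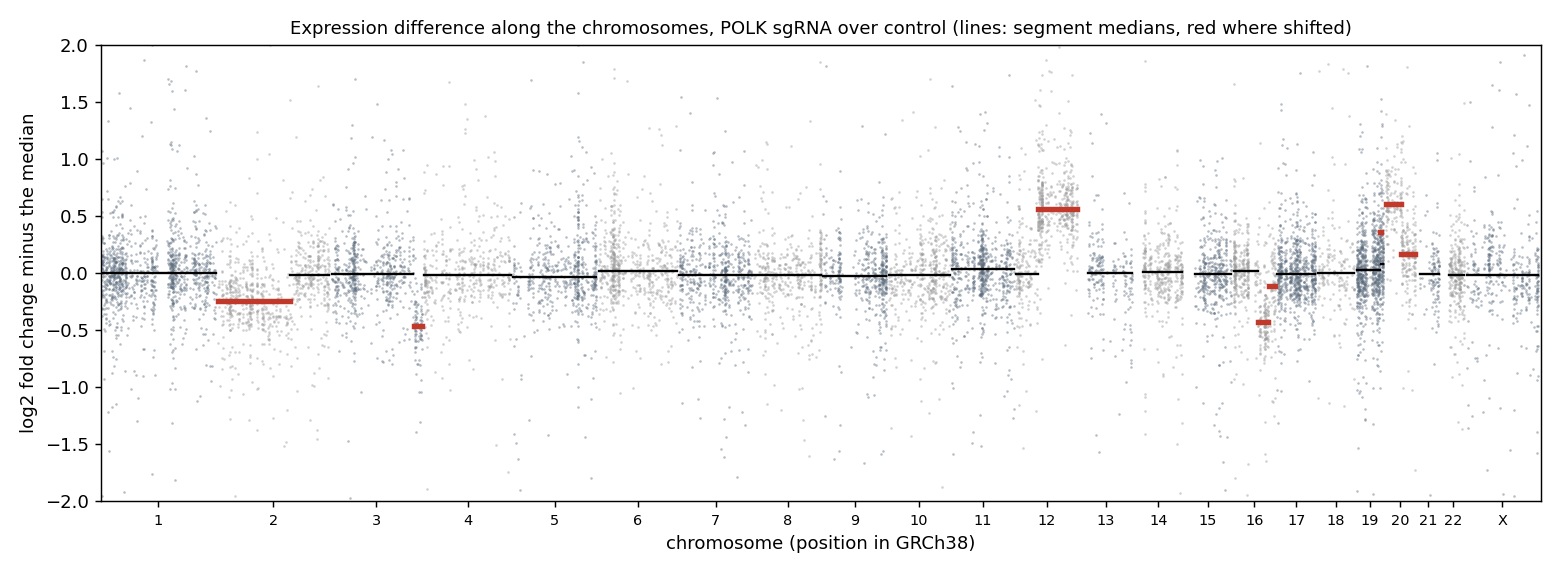
Log2 fold change of each gene minus the median of all genes (y axis) by position on chromosomes 1 to 22 and X (x axis, GRCh38), from 3 POLK sgRNA and 3 control libraries; points are genes, lines are segment medians, red where shifted by at least 0.1, and 134 genes beyond 2 are not drawn. The longest stretches lie at 0.56 on chromosome 12 and at −0.25 on chromosome 2.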

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

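The removal of shifted segments, the subtraction of their medians and the tests against a minimum fold were chosen after seeing the data. POLK was lower under every setting run, with a log2 fold change of −0.40 to −0.32 on leaving out 1 library. Leaving out 1 library gave 4181 to 4441 genes higher with POLK sgRNA, 4091 to 4286 genes lower with POLK sgRNA, 992 to 1029 genes changed at least 2-fold with POLK sgRNA and 7 to 8 lists. DESeq2 gave 3988 higher, 4020 lower and 1054 at least 2-fold, with 984 adjusted p-values not given. Depending on the setting, 87.9 to 98.7% of the 8962 calls were kept and none reversed. The 115 genes named by the rule set beforehand were tested under 13 settings, except OCA2, TYRP1 and CD14 under the filter on a mean CPM of 1. Of these none reversed, and MT-ND1 and MT-ND6 alone lost the call, each on leaving out 4 of the 6 libraries in turn. Of 43 genes named after their values were seen, which gave 554 tests, none reversed. POLH lost the call with library size alone (adjusted p = 0.10), no filter (0.072), the block (0.056), DESeq2 (0.12) and on leaving out 4 of the libraries in turn, and COL1A2 on leaving out control library 1 (0.077) or POLK sgRNA library 1 (0.074) or 2 (0.054). B2M, COL1A1 and HBD passed on leaving out 1 control library (0.034, 0.016 and 0.017). A filter on a mean CPM of 1 kept 12344 genes and left 525 changed at least 2-fold in place of 953. Many of the 953 therefore had a mean under 1 CPM. Against a minimum log2 fold change of 0.32, 1653 were higher and 1224 lower, and against a fold of 2, 543 passed, by the construction of these tests.

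The 7 list calls held under 13 of 14 settings of camera each, and none held with an estimated correlation, which called 0 lists of 31 in limma's camera, where the interferon response, p53 targets and dedifferentiated melanoma state had unadjusted p-values of 0.0073, 0.023 and 0.026 and the other 28 lists had none under 0.05. Fry called 24 lists in one direction and 31 in either direction, since it does not compare a list with other genes. The replicate numbers do not pair the libraries, as same-numbered libraries deviated with correlations of −0.013, −0.036 and 0.013 and 1 of 6 libraries correlated best with its own number. With the replicate number as a block, the POLK log2 fold change was −0.36, there were 4483 genes higher with POLK sgRNA, 4290 genes lower with POLK sgRNA and 952 genes changed at least 2-fold with POLK sgRNA, and 10 lists passed. Depth limits genes near 3 counts in a library, a level of 0.0525 to 0.0700 CPM.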

Other observations

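The lists in the next 2 paragraphs, and the tests of chromosome 5, of the collagens and of erythroid genes without EPOR, were chosen after the results were seen. The adjusted p-values of these lists do not account for that choice, so they describe the lists and lend them no separate support.

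The summed leukocyte markers, mainly CD68 and LYZ, were at 21.9 ± 0.02 CPM in control and 62.6 ± 1.05 CPM in POLK sgRNA libraries, but of 6 tested 2 rose and 1 fell. All 15 tested genes of HLA class II antigen presentation rose, with a median log2 fold change of 0.70. The invariant chain gene CD74 rose from 1084 to 1746 CPM, HLA-DRB1 from 79.0 to 147 CPM, HLA-DOA from 6.19 to 20.5 CPM and CIITA, the regulator of this group, from 53.3 to 63.5 CPM. HLA-DQA1 and HLA-DQA2 rose by 2.92 and 2.98 on the log2 scale, but are near-identical and uncertain. The list was higher in camera with the preset correlation (adjusted p = 1.9e-06 over 5 lists) and not with an estimated correlation (adjusted p = 0.078). Of 15 HLA class I presentation genes 11 rose, including HLA-B (111 to 202 CPM), HLA-C (151 to 254 CPM) and TAP1 (29.6 to 42.8 CPM). The annotated spans of HLA-B and HLA-C overlap, and TAP1 lies within that of PSMB9, so these genes may share reads and are uncertain. The 2 that fell, PSMB10 and NLRC5, lie in a lowered segment of chromosome 16. B2M was at 415 and 406 CPM and did not pass in edgeR's quasi-likelihood test, except on leaving out control library 1 (adjusted p = 0.034). The list passed in camera with the preset correlation (adjusted p = 0.0075) and not with an estimated correlation (adjusted p = 0.15).

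Of 33 cancer-testis genes on the X chromosome 21 rose and 5 fell (camera, adjusted p = 0.00058, and adjusted p = 0.054 with an estimated correlation). MAGEA4 rose from 796 to 1019 CPM and MAGEC1 from 0.0911 to 1.27 CPM, while MAGEA3 fell from 171 to 152 CPM. Many of these genes have close copies and are uncertain. In the beta-globin locus on chromosome 11, HBE1 rose from 0.727 to 23.9 CPM, HBG2 from 0.486 to 10.3 CPM and the neighbouring receptor genes OR51B4 and OR51B5 from 0.283 to 5.84 and 0.119 to 1.68 CPM, while HBB (2.00 and 1.82 CPM) and HBD (2.63 and 2.19 CPM) did not pass, except HBD on leaving out control library 2 (adjusted p = 0.017). The annotated spans of HBE1 (5268345 to 5505652) and HBG2 (5253190 to 5505605) overlap, and OR51B4 (5301014 to 5301946) lies within both. These genes may share reads, so their rises are uncertain as separate events. Of 9 HOXC genes, all within the raised segment of chromosome 12, 7 rose, with HOXC12 furthest.

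Blocks of neighbouring genes shifted together on 6 chromosomes, in all 3 POLK sgRNA libraries. Removing a smooth trend on GC content, transcript length and expression level, which explained 1.75% of the variance, left the median of the chromosome 12 segment at 0.56, which argues against these as the cause. The median of chromosome 5 beyond POLK was −0.021, which argues against a loss of that arm at the targeted site. A different DNA copy number in the cells of the 2 groups may account for the shift on chromosome 12: genes of the chromosome 12 segment spread about as widely as genes outside shifted segments, with a ratio of median absolute deviations of 0.989. The ratio was 0.79 to 1.15 in 6 other shifted segments. It was 1.38 on chromosome 16 from 77.2 Mb, where 65.3% of genes shared the direction. On chromosome 19 the median was 0.67 in the less and 0.29 in the more expressed genes, so these 2 segments moved less evenly. A ratio near 1 would follow from any even shift and does not single out copy number. Without a measurement of DNA, whether copy number differed stays open for all shifted segments. Whether POLK editing or the history of the cells gave any such difference stays open too.

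The globin genes HBE1 and HBG2 and the matrix genes LUM and DCN rose from low levels, which could come from other cells in the cultures. HBE1 and HBG2 overlap in the annotation and may share reads, so the HBG2 level used below is uncertain. Of 14 erythroid genes outside the globin locus, summed CPM rose by 2.35, above a bound of 1.03 CPM set beforehand from the HBG2 level, so this test was met, but EPOR, already at 11.3 CPM in control cells, alone rose by 3.15 CPM. Without EPOR the sum changed by −0.797 CPM, and HBA1 was at 0.251 and 0.0557 CPM, which argues against erythroid cells as the whole source. COL1A1, COL1A2 and COL3A1, abundant in fibroblasts, summed to 4.62 ± 1.34 and 4.74 ± 0.95 CPM, a change of 0.122 CPM against 5.10 CPM for LUM and DCN, which argues against fibroblasts as the whole source. COL6A3, another fibroblast marker, rose from 1.15 to 7.68 CPM, its source stays open, and no biological explanation was tested.

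In 40 genes the mean was under 0.1 CPM in one group and at least 1 CPM in the other, 19 of them on with the POLK sgRNA and 21 off. Of these genes 10% lie in shifted segments, against 13.3% of tested genes, which argues against the shifted chromosome segments as their cause. Whether POLK editing or a difference between the founding cells of each group switched them was not tested, and independently edited cells would bear on it.

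The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes changed, 1 split, the real one, gave as many as 8962, and the highest other gave 0. For genes changed at least 2-fold, 1 split gave as many as 953, and the highest other gave 0. Each other split puts libraries of both groups on each side, so the group difference becomes spread within sides. A count of 0 was therefore likely in advance and does not show that the libraries are independent. For the 7 lists called with the preset correlation, 2 splits gave as many, and the highest other gave 9 lists, in a split that joined control library 1 with POLK sgRNA libraries 1 and 2. Every other split called at least 1 list while calling 0 genes. Each other split keeps part of the group difference, since each side holds 2 libraries of one group and 1 of the other. Camera ranks a list against other genes and can call lists from that part. The number of lists was thus not highest in the real grouping, but these splits cannot decide whether chance gives as many.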
